A study of Mus musculus with 8 samples.

How the data were processed

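The series holds 8 single-cell RNA libraries from the lungs of C57BL6/J mouse pups, 4 from pups kept in air and 4 from pups kept in hyperoxia, per the labels. Per the labels' protocols, lungs were taken at 5 days of age, frozen in a DMSO and serum medium, thawed, stained and sorted by flow cytometry for endothelial, epithelial and immune cells, and the libraries were made with a droplet-based 3' kit that tags each captured molecule with a unique molecular identifier (UMI). The values used were the deposited UMI counts, whole numbers per gene and cell that had not been normalized, in a single table of 32285 genes and 11806 cells with 77020720 UMIs in total. Cell Ranger 1.3.1 and the mouse build mm10 are named in the submitters' processing notes. The version number is printed as given there, and the count settings, including the handling of strand and intronic reads, are not given in the sources used here. The deposited counts came from cells that had already been filtered, as the values show: the lowest number of genes in any cell was 800, the highest mitochondrial share was 9.99% and the highest number of UMIs was 39865. UMI counting removes copies made in amplification, but it does not remove RNA that was free in the cell suspension and was captured in droplets of other cells.

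The column names of the table gave a cell barcode and a suffix left by merging, with 7 different suffixes. The barcodes were in alphabetical order within stretches, and the order started again often enough to give 8 stretches, called runs of barcodes here. Of the 8 libraries, 0 had a label that matched a column name, a suffix or a run. Cells were therefore assigned to no library and to no oxygen group, and the table was treated as 1 pooled sample. The tests fixed before the data were examined all needed that assignment and could not be run: genes changed between hyperoxia and air per cell class, gene lists moved between the groups, shares of classes between the groups, and the difference of response between classes. No p-value, standard error or count of changed genes is given for that reason, and no run was assigned to an oxygen group from its order or its values. The analysis instead describes which cell classes were present and where the genes of the fixed lists were expressed. Values per run are given singly or as a range with the median, since a run is no known replicate of a group.

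The cell filter fixed in advance, at least 300 genes and at most 15% mitochondrial counts, removed 0 cells. Doublets were scored in each run with Scrublet as implemented in scanpy 1.11.5, with 20 principal components and an expected doublet share of 5%. The automatic threshold marked 58 cells, or 0.491%, which was taken as a failed threshold. The cells with the highest scores were then removed at a rate of 0.8% per 1000 cells of a run, which took out 193 cells and kept 11613. Free RNA was not subtracted. Its level is read from transcripts of other cell types that are given beside the results.

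For clustering, counts were scaled to 10000 per cell and log transformed, 2000 variable genes were chosen, and 30 principal components, scaled values limited to 10, a graph of shared nearest neighbours with 20 neighbours and Leiden clustering at resolution 1.0 gave 28 clusters. Genes of the fixed lists that were not cell type markers took no part in the clustering, nor did sex-linked, haemoglobin and mitochondrial genes, so their levels in a cluster were not used to build it. A cluster was named only from markers of 35 cell types fixed before the data were examined. The type with the highest marker score was used where at least 3 of its markers lay at least 2 times above the mean of the clusters, where its markers among the 10 leading genes were not outnumbered by those of a type of another compartment, and where its score stood at least 0.3 above that of any type of another compartment, on a log2 scale with a pseudocount of 10 CPM. Names carry the ending "-like" for that reason, and 5 clusters stayed unnamed. The scoring rule, the margin of 0.3, the 20 neighbours, the doublet rate and the joining of both conventional dendritic types under a single name were chosen after the data had been seen. Across 6 clustering settings at least 93.6% of the cells kept the class they had in the chosen setting. The margin kept cluster 26, with 4.12% of the kept cells, out of the neuroendocrine class, and the 4 alternatives that changed the cell filter, the doublets, the resolution or the neighbours each separated 14 to 17 neuroendocrine-like cells as a cluster of their own.

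Counts were summed over all kept cells of a class and expressed as CPM, the usual unit of counts scaled to a fixed total, here the total of that class. The fold of a gene is its CPM in the class where it was highest, its leading class, over its CPM in all other kept cells together. The leading class was picked for being highest, so the fold describes where a transcript was found and is no test. Intervals are exact 95% intervals: Poisson for CPM, conditional binomial for ratios and Clopper-Pearson for shares of cells. They cover counting error only, and not the variation between animals, libraries or dissociations. A count of 0 was taken to allow up to 3 counts. Values within a run were used where a run had at least 20 cells of the class.

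The planned rule for naming genes rested on tests between the groups and could not be applied. In its place, a rule set after the values had been seen named, for each fixed list, up to 4 members that were not cell type markers, that reached at least 20 CPM in a leading class of at least 20 cells and that lay at least 4-fold above all other cells, by size of fold. The 8 genes of the type 2 immunity list that had been fixed by name in advance were added, 7 of which are also cell type markers. For pairs of classes, the up to 4 members of the lists with the highest CPM on each side were named among those at least 4-fold apart. The values of 1 gene that this rule named are not reported here, and the counts of genes and ratios include it. The 19 lists covered immune polarization, interferon and inflammatory responses, p53, NRF2 and HIF targets, the cell cycle, angiogenesis, surfactant and lipid synthesis, MHC class II, matrix, metallothioneins, immediate early genes, and transcripts that report on mitochondria, red cells, free surfactant RNA, mesenchyme and neutrophils. Gene positions are from GENCODE vM21, an annotation of the same assembly as mm10, counted from 1.

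Alternatives were to keep the doublets, to require at least 1000 genes and at most 5% mitochondrial counts, to cluster at resolution 2.0, to use 15 neighbours, to divide by all kept cells, to leave out cluster 26, or cluster 22 for ratios of alveolar macrophage-like cells, and to leave out each run in turn. Those for 15 neighbours, clusters 22 and 26, the runs, the gene folds, the ratios between classes, the list counts and list sums, and the shares of the smaller classes were added after the data had been seen. On simulated counts for 13174 genes with the depth of the alveolar type 2-like class against all other cells, with 200 genes changed, 95.5% of the true ratios lay inside their interval, and true ratios of 2, 4 and 8 were estimated at medians of 1.99, 4.01 and 8.02. In 4000 simulated cells, 96.6% of the cells of named types received their class and 100% of those of an unnamed type stayed unnamed. These cells were drawn from the mean profile of the class already given, without variation within a class or doublets. The simulated counts followed the same Poisson model as the intervals. Both simulations therefore check the calculation only, and not the names or the intervals in real cells. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.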

Results

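Single-cell RNA profiles were collected from sorted endothelial, epithelial and immune cells of lungs from 5-day-old C57BL6/J mouse pups. All pups had been exposed to lipopolysaccharide, a bacterial cell wall component that causes inflammation, at day 14 of gestation, per the labels. After birth they were kept in 21% oxygen (air, 4 libraries) or in 65% oxygen (hyperoxia, 4 libraries), a combination used as a model of bronchopulmonary dysplasia, the chronic lung disease of preterm infants. The study asked how type 2 immune polarization relates to that disease. The count table pooled all libraries without a key from cells to libraries, so hyperoxia and air were not compared, and the values describe the lung cells of both groups together. The table held 11806 cells with a median of 4425 UMIs and 1815 genes per cell. Its 8 runs of barcodes held 1570, 282, 1002, 1663, 1887, 1712, 3355 and 335 cells, and 17841702, 3697021, 6555221, 7363899, 11298868, 12516553, 15173429 and 2574027 UMIs. The median number of UMIs per cell ranged from 3246 in run 4 to 11587 in run 2. There are no known replicates of a group, and all intervals are 95% intervals for counting error only.

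Immune cells made up most of the sorted material. Of the 11613 cells kept, 8235 (70.9%, 70.1 to 71.7) belonged to 12 immune-like classes, 901 (7.76%, 7.28 to 8.26) to 3 epithelial-like classes and 631 (5.43%, 5.03 to 5.86) to 4 endothelial-like classes. Alveolar macrophage-like cells were the most numerous immune class, with 2079 cells or 25.2% of the immune cells (24.3 to 26.2). Nonclassical monocyte-like cells followed with 21.0% (20.1 to 21.9), classical monocyte-like cells with 17.0% (16.2 to 17.9) and neutrophil-like cells with 8.40% (7.81 to 9.02). Without run 5 the order of the first 2 turned, with nonclassical monocyte-like cells at 21.4% and alveolar macrophage-like cells at 20.6%. T-like cells made up 8.14% of the immune cells, interstitial macrophage-like cells 6.89%, natural killer-like cells 4.03%, conventional dendritic-like cells 3.30%, gamma-delta T-like cells 2.64%, B-like cells 1.85% and migratory dendritic-like cells 0.619%. Type 2 innate lymphoid-like cells (innate lymphoid 2-like in the plots), a rare class that makes type 2 cytokines, numbered 71, or 0.862% of the immune cells (0.674 to 1.09). With 15 neighbours natural killer-like cells made up 7.28% and T-like cells 4.85% of the immune cells, and T-like cells made up 4.98% under the stricter cell filter. Interstitial macrophage-like cells made up 3.11% at resolution 2.0 and 4.39% without run 6, and B-like cells 0.559% without run 7. The remaining 1846 cells (15.9%) fell in 5 clusters that took no name from the fixed markers. Of these, clusters 2, 13, 7 and 27, with 540, 466, 254 and 108 cells, held the leukocyte gene Ptprc at 620, 606, 2600 and 998 CPM. Interstitial macrophage-like cells held it at 616 CPM. The immune share and all shares of the immune cells leave these clusters out, so the share of leukocytes in the table may be higher.

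General capillary-like cells were the largest endothelial class, with 339 cells or 53.7% of the endothelial cells (49.7 to 57.7). Car4 capillary-like cells, the type that lies close to the alveolar epithelium, made up 29.3% (25.8 to 33.0), arterial-like cells 10.5% and lymphatic-like cells 6.50%, a class that held 0 cells with doublets kept. Among the epithelial cells, surfactant-producing alveolar type 2-like cells made up 87.6% (85.2 to 89.7), the flat alveolar type 1-like cells 10.1% (8.21 to 12.3) and ciliated-like cells 2.33%, with only 21 cells. The alveolar type 2-like class also held Scgb1a1, a fixed marker of secretory cells, at 2614 CPM, the highest of all classes. At resolution 2.0, clusters of 501 and 288 cells took that name. The smaller was led by Scgb1a1, and secretory was its second type, at a score of 1.58 against 3.40. The class may thus include secretory cells, and the genes it led were not assigned to either type. The sort set the proportions between the compartments, and each of these classes was given as a share of its own compartment. Alveolar type 1-like cells made up 6.41% of the epithelial cells without run 1, and 20% with doublets kept, 19.2% under the stricter cell filter or 20.7% with 15 neighbours. In these 3 settings 107 of 108, 69 of 71 and 108 of 108 of the cells of the unnamed cluster 27 that passed the filter were named alveolar type 1-like.

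The runs of barcodes differed in composition by more than the counting error. Cells of the named immune classes ranged from 50.1% to 84.3% of the kept cells of a run, with a median of 70.8%. Epithelial cells ranged from 4.57% to 14.7% and endothelial cells from 2.11% to 6.77%. These ranges leave out the unnamed clusters. In run 8 named immune cells made up 58.1%, and cluster 2, which held Ptprc, made up 21.0%. Alveolar macrophage-like cells ranged from 4.26% to 35.9% of the kept cells of a run and classical monocyte-like cells from 3.85% to 22.1%. Neutrophil-like cells ranged from 0.161% in run 5 to 27.1% in run 1, and without run 1 their share of the immune cells was 3.78% in place of 8.40%.

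**Figure D1:**
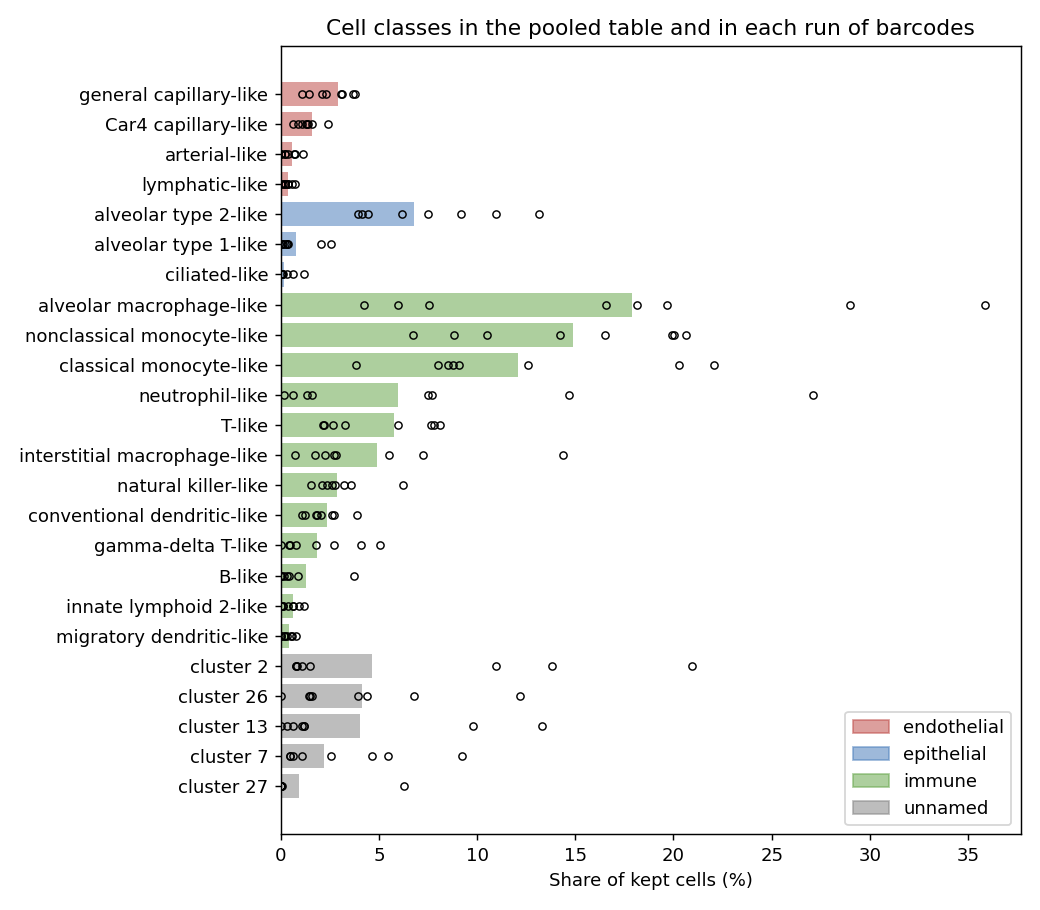
Share of kept cells (x axis, percent) for each cell class or unnamed cluster (y axis). Bars give the pooled table, coloured by compartment, and circles give the 8 runs of barcodes. The circles of neutrophil-like cells spread from 0.161% to 27.1%, while those of general capillary-like cells lie between 1.11% and 3.78%.

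Type 2 immunity was the study's stated subject. Summed over the list, its genes were highest in type 2 innate lymphoid-like cells, at 2764 CPM (2597 to 2939), followed by migratory dendritic-like cells at 1786 CPM and alveolar macrophage-like cells at 1329 CPM, and they were found in all 24 classes and clusters. Without cell type markers the sum was highest in alveolar type 2-like cells, at 421 CPM. Il33, an alarmin released by barrier cells (chromosome 19, 29925114 to 29960718, plus strand in mm10), was highest in alveolar type 2-like cells, at 256 CPM (243 to 270), which was 100-fold higher than in all other cells (85.7 to 118) and higher in 8 of 8 runs. The next class was migratory dendritic-like cells, at 45.8 CPM, while alveolar type 1-like cells held 5.52 CPM of Il33 and Car4 capillary-like cells 9.63 CPM. Retnla, a secreted protein induced by type 2 cytokines, led in alveolar type 2-like cells too, at 106 CPM (97.7 to 115), 310-fold above all other cells (206 to 488) and higher in 8 of 8 runs. The receptor genes Il9r and Klrg1 led in type 2 innate lymphoid-like cells, at 81.7 CPM (55.1 to 117) and 65.4 CPM (41.9 to 97.2).

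The receptor for Il33, Il1rl1, reached 607 CPM in type 2 innate lymphoid-like cells, and the transcription factor Gata3 reached 651 CPM. The cytokines Il13, Il5 and Il4 were found there at 139 CPM (103 to 183), 120 CPM (87.1 to 161) and 57.2 CPM (35.4 to 87.4). The genes lie near each other on chromosome 11, Il4 at 53602982 to 53618669, Il13 at 53631324 to 53634702 and Il5 at 53720794 to 53725106. These 5 genes are cell type markers, so their place in this class follows in part from how clusters were built and, except for Il4, named. Il4 is a fixed marker of basophils, the type with the second-highest score in this cluster, at 1.67 against 3.14. Areg, a growth factor and also a marker, was highest in ciliated-like cells at 782 CPM (661 to 918), with 496 CPM (426 to 573) in type 2 innate lymphoid-like cells. Arg1, the arginine-degrading enzyme, was at 376 CPM (316 to 444) in type 2 innate lymphoid-like cells and at 356 CPM (342 to 371) in cluster 2, values whose intervals overlap. Of the 28 members of the list, 22 reached 20 CPM in their leading class and 19 of those lay at least 4-fold above all other cells, of which 4 were no cell type markers. The most frequent leading class was type 2 innate lymphoid-like cells, with 9 members.

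In alveolar type 2-like cells, the log2 fold of Retnla was 8.28, with 8.87 without run 7 and 7.62 under the stricter cell filter, and that of Il33 was 6.65, and 7.50 without cluster 26. There were 71 type 2 innate lymphoid-like cells, of which 39 were in run 7. Of the genes named in that class, the log2 fold of Il9r was 8.00, and 8.95 without run 7, and that of Klrg1 was 6.67, and 7.31 without run 3. That of Il4 was 8.26, and 7.19 without run 7, and that of Arg1 was 3.10, and 3.74 without run 1. The fold of Il13 was 10.35, with 11.39 without run 1 and 9.08 without run 5, and that of Il5 was 11.13, with 11.81 without run 1 and 11.77 without run 5.

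**Figure D2:**
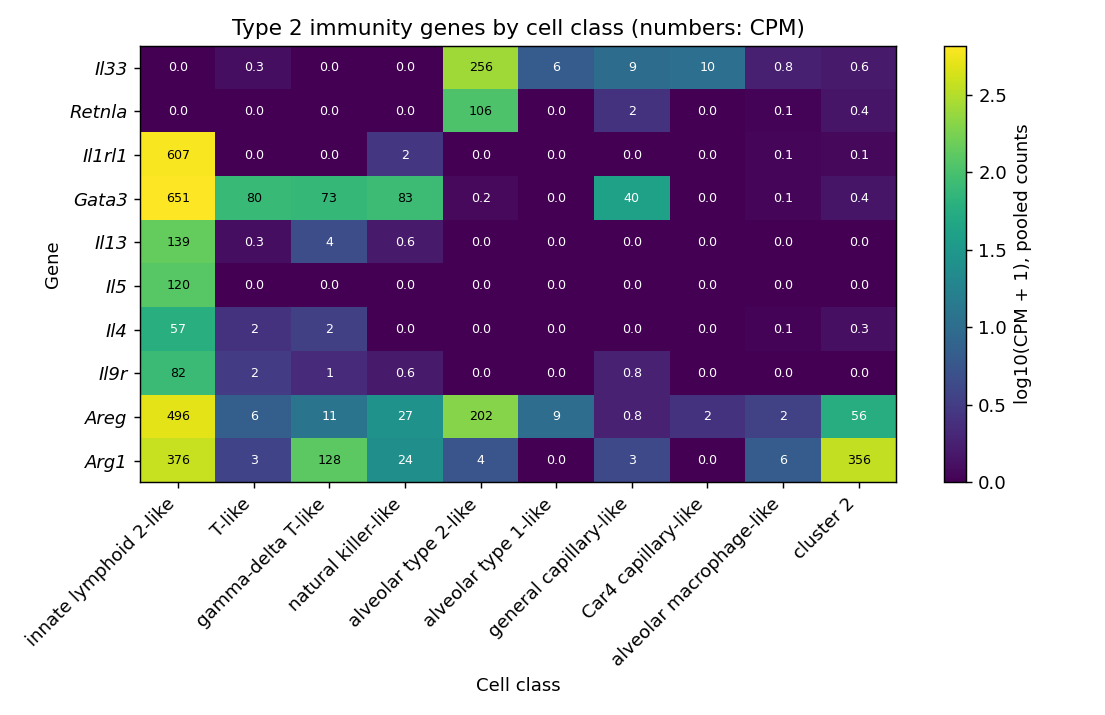
A selection of genes of the type 2 immunity list (y axis) in a selection of cell classes (x axis). Ciliated-like cells, where Areg was highest at 782 CPM, are not shown. Nor are migratory dendritic-like cells, which came second for Il33 at 45.8 CPM. The colour gives log10 of CPM plus 1 from pooled counts and the number in each field gives CPM. Il33 stands at 256 CPM in alveolar type 2-like cells, and Il13 and Il5 stand at 139 and 120 CPM in innate lymphoid 2-like cells.

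Type 1 immunity genes were expressed by natural killer-like and migratory dendritic-like cells. Ifng, the defining type 1 cytokine, was at 314 CPM (288 to 342) in natural killer-like cells, 71.3-fold above all other cells (62.0 to 82.2) and higher in 6 of 6 runs, with 83.5 CPM in gamma-delta T-like and 48.0 CPM in T-like cells. Il12b, a subunit of a cytokine that drives Ifng production, reached 1212 CPM (1096 to 1338) in migratory dendritic-like cells against 5.80 CPM in conventional dendritic-like cells. The chemokine Ccl5 reached 13188 CPM in migratory dendritic-like cells and 4474 CPM in natural killer-like cells. Il12rb1, a receptor chain for Il12, led in gamma-delta T-like cells at 48.1 CPM (38.1 to 59.98). Of the 21 members in the table, 20 reached 20 CPM and 18 of those were at least 4-fold above all other cells, with natural killer-like cells leading for 8. The log2 fold of Il12b was 12.67, with 14.21 without run 6, 11.97 without run 7 and 14.36 under the stricter cell filter, and it rests on 51 migratory dendritic-like cells.

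Type I interferon response genes were highest in monocytes when summed, at 2968 CPM (2931 to 3006) in classical monocyte-like and 1761 CPM in nonclassical monocyte-like cells. Ifi27l2a contributed most, at 1899 CPM (1870 to 1929) in classical monocyte-like cells, 8.38-fold above all other cells (8.19 to 8.57) and higher in 8 of 8 runs. Ifit2 and Ifit3 led in alveolar type 1-like cells at only 47.8 CPM (31.3 to 70.1) and 31.3 CPM (18.2 to 50.1). Ifi44 led in general capillary-like cells at 24.0 CPM (16.2 to 34.3), with 19.3 CPM in lymphatic-like cells. Of the 21 members in the table, 20 reached 20 CPM and 14 of those were at least 4-fold above all other cells, with classical monocyte-like cells leading for 7. The log2 fold of Ifi44 was 5.94, and 7.002 without run 6.

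Inflammatory and NF-kB response genes were led by neutrophil-like cells, which held 126842 CPM of the summed list. That sum rests mainly on S100a8 and S100a9, calcium-binding proteins that are also neutrophil markers, at 57898 and 54675 CPM. Among members that are no markers, Lcn2, an iron-sequestering protein, was at 2574 CPM (2523 to 2626) in neutrophil-like cells and at 919 CPM in alveolar type 2-like cells. Il1r2, a decoy receptor for interleukin 1, was at 821 CPM (792 to 850) in neutrophil-like cells, 21.3-fold above all other cells (20.2 to 22.4). Saa3, an acute phase protein, led in cluster 2 at 1237 CPM (1210 to 1264), 13.1 times its level in neutrophil-like cells and above all other cells in 3 of 4 runs. Sele, an adhesion molecule for leukocytes, led in arterial-like cells at 136 CPM (91.9 to 194). Of the 25 members, 23 reached 20 CPM and 19 of those were at least 4-fold above all other cells, with neutrophil-like cells leading for 12. On the log2 scale the fold of Saa3 was 6.08, and 4.196 without run 1, that of Lcn2 was 4.83, and 5.44 without run 6, and that of Sele was 7.62, with 9.26 without run 1, 6.13 without run 5 and 9.29 under the stricter cell filter.

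Among NRF2 targets, which serve antioxidant defence, Gclc, the rate-limiting enzyme of glutathione synthesis, and Me1, which makes NADPH, led in alveolar type 2-like cells at 551 CPM (531 to 571) and 263 CPM (250 to 277). Gsta4, a glutathione transferase, led in cluster 26 at 395 CPM, and Gpx2, a glutathione peroxidase, in ciliated-like cells at 79.2 CPM (44.3 to 131). Of the 26 NRF2 targets, 23 reached 20 CPM and 8 of those were at least 4-fold above all other cells, with ciliated-like cells the most frequent leading class, for 6. Summed over the list, cluster 2 held 30856 CPM, cluster 13 25409 CPM and alveolar macrophage-like cells 25148 CPM. The metallothioneins Mt1 and Mt2, zinc-binding proteins, both led in ciliated-like cells, at 6227 CPM (5877 to 6593) and 988 CPM (851 to 1140). On leaving out any of runs 3, 4, 6, 7 and 8, the ciliated-like class, of 21 cells, fell under the 20 cells needed to lead. The count of metallothioneins at least 4-fold above all other cells was then 1 in place of 2. That count was taken with other classes leading and reports no change in ciliated-like cells. Without cluster 26 the log2 folds of Me1, Gpx2 and Mt2 were 7.24, 7.72 and 4.47, against 5.53, 5.60 and 3.25 with it.

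Among p53 targets, Plk2 and Phlda3 led in Car4 capillary-like cells at 576 CPM (518 to 639) and 169 CPM (138 to 204), each higher in 5 of 5 runs. For Plk2 the general capillary-like cells followed closely, at 459 CPM. Psrc1 led in cluster 26 at 82.8 CPM and Dcxr in ciliated-like cells at 660 CPM. Of the 25 p53 targets, 24 reached 20 CPM and 11 of those were at least 4-fold above all other cells, with cluster 26 leading for 8. Among HIF targets and glycolysis genes, Vegfa, the main growth factor for endothelial cells, was at 1789 CPM (1678 to 1905) in alveolar type 1-like cells, 55.0-fold above all other cells (51.0 to 59.2). Ndrg1 led in lymphatic-like cells at 373 CPM (283 to 482), Ankrd37 in ciliated-like cells at 73.9 CPM and Egln3, an oxygen-sensing hydroxylase, in neutrophil-like cells at 32.0 CPM (26.5 to 38.2). Of the 24 members of that list, 22 reached 20 CPM and 8 of those were at least 4-fold above all other cells, with cluster 26 leading for 11. The log2 fold of Vegfa was 5.78, and 5.14 with 15 neighbours or with doublets kept, that of Ndrg1 was 5.19, and 4.56 under the stricter cell filter, and that of Phlda3 was 3.73, and 4.38 without cluster 26.

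Cell cycle genes were led by cluster 26 for 23 of the 40 members, and 34 of the 40 members lay at least 4-fold above all other cells in their leading class. Cenpf, a kinetochore protein, was at 223 CPM (211 to 235) in cluster 26 and at 144 CPM in gamma-delta T-like cells. Bub1, Ccnb1 and Hmmr, which act in mitosis, led in cluster 26 at 60.6, 84.7 and 100 CPM. Summed over the list, however, gamma-delta T-like cells held most, at 7343 CPM (7212 to 7475), followed by natural killer-like cells at 7213 CPM (7084 to 7344), values whose intervals overlap. Cluster 22, of 83 cells and led by cell cycle genes such as Pclaf and Top2a, was summed within the alveolar macrophage-like class. It could therefore not lead by itself. Immediate early and heat shock genes, which respond to dissociation and thawing as well as to injury, were led by arterial-like cells for 7 of 20 members, and 10 of the 20 lay at least 4-fold above all other cells. Jun was at 2088 CPM (1902 to 2288) and Hspa1b at 68.1 CPM (38.1 to 112) in arterial-like cells, while Hsp90aa1 and Hspb1, heat shock proteins, led in cluster 26 at 3417 and 650 CPM. Hspa1b is nearly identical in sequence to Hspa1a, so its counts are uncertain, and its log2 fold of 2.86 was 2.25 without run 7.

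Angiogenesis and endothelial signalling genes were led by endothelial classes for 27 of 31 members, and arterial-like cells led for 11. Edn1, the vasoconstrictor endothelin, was at 708 CPM (601 to 828) in arterial-like cells and at 220 CPM in general capillary-like cells. Tek, the receptor for angiopoietins, did not differ detectably between general capillary-like cells, at 697 CPM (651 to 745), and arterial-like cells, at 690 CPM. Its ligand Angpt2 was at 167 CPM (109 to 245) in lymphatic-like cells and at 9.62 CPM in general capillary-like cells. Esm1, a proteoglycan of growing vessels, was highest in the 21 ciliated-like cells at 47.5 CPM (21.7 to 90.2), from 9 counts, with 27.3 CPM in general capillary-like cells. All 31 members reached 20 CPM and 29 were at least 4-fold above all other cells.

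Surfactant and lipid synthesis genes were led by alveolar type 2-like cells for 17 of 22 members, and the list made up 152689 CPM of their counts. Sftpd, a surfactant protein of innate defence (chromosome 14, 41172214 to 41185149, minus strand), was at 2313 CPM (2272 to 2354), 338-fold above all other cells (309 to 371) and higher in 8 of 8 runs. Lpcat1, which makes surfactant phospholipid, was at 1247 CPM, Scd1, a fatty acid desaturase, at 859 CPM and Etv5, a transcription factor of these cells, at 600 CPM, each higher in 8 of 8 runs. All 22 members reached 20 CPM and 17 were at least 4-fold above all other cells. The log2 fold of Sftpd was 8.40, and 9.61 without run 6. Without cluster 26, those of Etv5 and Scd1 were 6.76 and 7.62, against 5.20 and 6.77 with it.

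MHC class II genes, which present antigen to T cells, were led by conventional dendritic-like cells for 7 of 12 members, and all 12 reached 20 CPM, with 11 at least 4-fold above all other cells. H2-Ab1 was at 5273 CPM (5170 to 5377), H2-Aa at 4882 CPM and H2-Eb1 at 4578 CPM in those cells, each higher in 5 of 5 runs. H2-Ob led in B-like cells at 132 CPM (105 to 164). The summed list held 28687 CPM in conventional dendritic-like, 16071 CPM in migratory dendritic-like (10073 CPM without run 1) and 11606 CPM in interstitial macrophage-like cells. The log2 fold of H2-Ob was 6.45, and 7.04 without run 7, which held 121 of the 152 B-like cells.

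Matrix and TGF-beta response genes were led by endothelial classes for 15 of the 24 members in the table, lymphatic-like cells leading for 6. Eln, which encodes elastin (chromosome 5, 134702593 to 134747323, minus strand), was at 19229 CPM (18654 to 19817) in arterial-like cells, 827-fold above all other cells (782 to 875) and 17.4 times its level in general capillary-like cells. Lox, which crosslinks elastin and collagen, was at 227 CPM (168 to 299) in arterial-like cells. Itgb6, an integrin that activates TGF-beta, was at 747 CPM (676 to 823) in alveolar type 1-like cells, and Tnc, a matrix glycoprotein, was at 109 CPM (63.7 to 175) in lymphatic-like cells. All 24 members reached 20 CPM and 21 were at least 4-fold above all other cells. On the log2 scale the fold of Lox was 8.30, and 7.63 without run 5, that of Itgb6 was 8.63, and 9.23 without run 6, and that of Tnc was 8.55, and 6.94 without run 1.

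The lists that report on other cells and on RNA quality gave the following levels. Surfactant transcripts were at 142658 CPM in alveolar type 2-like cells and at 49.0 CPM in alveolar macrophage-like, 109 CPM in T-like and 62.7 CPM in B-like cells, with 1175 CPM in general capillary-like, 1291 CPM in type 2 innate lymphoid-like and 8789 CPM in cluster 27 cells. The levels in T-like, B-like and general capillary-like cells were 69.2, 102 and 176 CPM without run 7, and that in type 2 innate lymphoid-like cells was 66.3 CPM without run 4 and 2245 CPM without run 7. All 5 members, which are Sftpc, Sftpb, Sftpa1, Sftpd and the secretory cell marker Scgb1a1, led in alveolar type 2-like cells. In the 21 ciliated-like cells, however, Sftpc alone was at 14752.5 CPM, and Sftpa1 was at 961 CPM. The levels given above for genes led by that class thus come from cells that also held these type 2 cell transcripts. Neutrophil transcripts led in neutrophil-like cells for 7 of 7 members and were at 1799 CPM in general capillary-like cells, but at 72.9 CPM there without run 3. Mesenchymal transcripts led in endothelial classes for the 7 of 9 members that reached 20 CPM, all 7 at least 4-fold above other cells, 5 of them in arterial-like cells. Postn, a matrix protein among them, led in lymphatic-like cells at 51.4 CPM (22.2 to 101) from 8 counts, with a log2 fold of 6.67 that was 5.90 without run 1, 8.82 without run 7, 5.93 under the stricter cell filter and 7.71 without cluster 26. Haemoglobin transcripts reached 20 CPM in no class for any of the 6 members, the highest summed level being 11.2 CPM in cluster 7, and 3.17 CPM there without run 1. Mitochondrial transcripts were at 13263 CPM in neutrophil-like cells and 50622 CPM in cluster 7, and none of the 13 members was 4-fold higher in its leading class.

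Both capillary classes were compared over the list genes that are no cell type markers. Of 189 genes compared, 34 were at least 4-fold higher in general capillary-like cells and 4 in Car4 capillary-like cells. Eln was 25.4-fold (17.4 to 38.7) and Tek 10.8-fold (7.90 to 15.3) higher in general capillary-like cells, and Stmn1, a microtubule regulator of dividing cells, 4.73-fold (3.56 to 6.40), each in 5 of 5 runs. Edn1 was found with 274 counts against 1 count in Car4 capillary-like cells, a ratio of 137 (24.3 to 5423). In Car4 capillary-like cells Timp3, an inhibitor of matrix proteases, was 4.56-fold higher (4.10 to 5.07) and the small heat shock protein Hspb1 6.08-fold (3.95 to 9.59), each in 5 of 5 runs. Nos2, the inducible nitric oxide synthase, was 6.01-fold higher there (2.08 to 21.1), from 15 counts against 5, in 4 of 5 runs. As log2 ratios of general over Car4 capillary-like cells, Eln was at 4.67, and 5.61 without run 1, and Nos2 at -2.59, and -1.70 without run 6.

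Of 162 genes compared between the alveolar epithelial classes, 34 were at least 4-fold higher in alveolar type 2-like and 19 in alveolar type 1-like cells. Sftpd was 62.8-fold (40.7 to 103), Lpcat1 8.26-fold (6.65 to 10.4) and Cd74, the MHC class II chaperone, 6.36-fold (5.20 to 7.88) higher in alveolar type 2-like cells. Lcn2 was found with 4948 counts there against 1 count in alveolar type 1-like cells, a ratio of 500 (89.6 to 19738). Vegfa was 17.5-fold (15.7 to 19.5), the growth factor receptor Igf1r 17.8-fold (15.3 to 20.6), Sparc, a collagen-binding protein, 9.67-fold (9.01 to 10.4) and Timp3 6.75-fold (6.18 to 7.36) higher in alveolar type 1-like cells. Each of these held in the 2 runs with at least 20 cells of both classes. As log2 ratios of alveolar type 2-like over type 1-like cells, Sftpd was at 5.97, with 5.30 without run 1, 3.97 with 15 neighbours, 3.58 with doublets kept and 4.61 under the stricter cell filter. Lcn2 was at 8.96, with 7.85 without run 6, and 5.36, 5.09 and 6.19 in the same 3 settings. Cd74 was at 2.67, with 2.003, 1.89 and 1.96 there, so that it was less than 4-fold apart in the last of these and with doublets kept. With 15 neighbours and with doublets kept, Vegfa, at -4.13, was at -3.45 and -3.46, Sparc, at -3.27, was at -2.59 in both, and Timp3, at -2.75, was at -2.08 and -2.13.

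Alveolar macrophage-like cells were compared with nonclassical monocyte-like cells over 165 genes, of which 24 were at least 4-fold higher in the macrophages and 21 in the monocytes. Alveolar macrophage-like cells expressed 23.6-fold more Mt1 (21.6 to 25.7), 11.8-fold more Fn1, which encodes fibronectin (10.8 to 12.9), 18.7-fold more Il18 (15.9 to 22.2) and 74.7-fold more of the matrix protein Spp1 (50.9 to 114). Nonclassical monocyte-like cells expressed 15.7-fold more Ifi27l2a (14.7 to 16.7), 7.06-fold more of the transcription factor Klf2 (6.69 to 7.45), 22.6-fold more Thbs1, which encodes thrombospondin (20.4 to 25.0), and 30.4-fold more of the p53 target Pmaip1 (26.1 to 35.7). All 8 genes differed in that direction in 8 of 8 runs.

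Interstitial macrophage-like cells held the MHC class II list members H2-Aa, H2-Ab1 and Cd74, named by the rule for pairs, far above alveolar macrophage-like cells. They expressed 29.99-fold more H2-Aa (27.7 to 32.5), 27.1-fold more H2-Ab1 (25.0 to 29.4), 23.4-fold more Cd74 (22.5 to 24.4) and 4.03-fold more of the chemokine Cxcl2 (3.89 to 4.18), each in 6 of 6 runs. Alveolar macrophage-like cells expressed 4.97-fold more Il18 (4.48 to 5.52), 4.87-fold more Spp1 (4.31 to 5.52), 5.90-fold more Stmn1 (4.98 to 7.04) and 8.87-fold more of the glutathione transferase Gstm1 (7.14 to 11.2), each in 6 of 6 runs. Of 166 genes compared, 11 were at least 4-fold higher in alveolar macrophage-like and 28 in interstitial macrophage-like cells. As log2 ratios of alveolar over interstitial macrophage-like cells, with doublets kept and under the stricter cell filter, H2-Aa, at -4.91, was at -4.16 and -4.26, H2-Ab1, at -4.76, was at -4.07 and -4.16, and Cd74, at -4.55, was at -3.82 and -3.86. The alveolar macrophage-like class joined clusters 4, 11 and 22, of 1215, 781 and 83 cells. Cluster 11 took the name at a marker score of 0.716, against 2.55 for cluster 4, with 1 alveolar macrophage marker among its 10 leading genes. Its leading genes Adamdec1 and Axl also led cluster 13, which stayed unnamed, and no ratio was computed without cluster 11. Cluster 22 was led by the cell cycle genes Pclaf, Stmn1 and Top2a, with no alveolar macrophage marker among its leading genes. It held Stmn1 at 1490 CPM. Without that cluster Stmn1 was 3.29-fold higher (2.77 to 3.95) in alveolar macrophage-like cells. The log2 ratio of Spp1 was 2.28, with 3.12 without run 1 and 1.53 at resolution 2.0.

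Few list genes separated the monocyte classes. Of 151 genes compared, 6 were at least 4-fold higher in classical and 1 in nonclassical monocyte-like cells. Classical monocyte-like cells expressed 14.2-fold more Fn1 (12.995 to 15.6), 5.48-fold more of the chemokine Ccl2 (4.59 to 6.58), 15.5-fold more Lcn2 (11.7 to 21.0) and 12.9-fold more of the mitotic gene Ube2c (8.54 to 20.5), each in 8 of 8 runs. Nonclassical monocyte-like cells expressed 7.18-fold more of the growth factor Pdgfb (4.87 to 10.9), in 7 of 8 runs. The log2 ratio of Lcn2 was 3.95, and 2.79 without run 1, and neutrophil transcripts summed to 6811 CPM in classical monocyte-like cells, and to 2899 CPM without run 1.

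**Figure D3:**
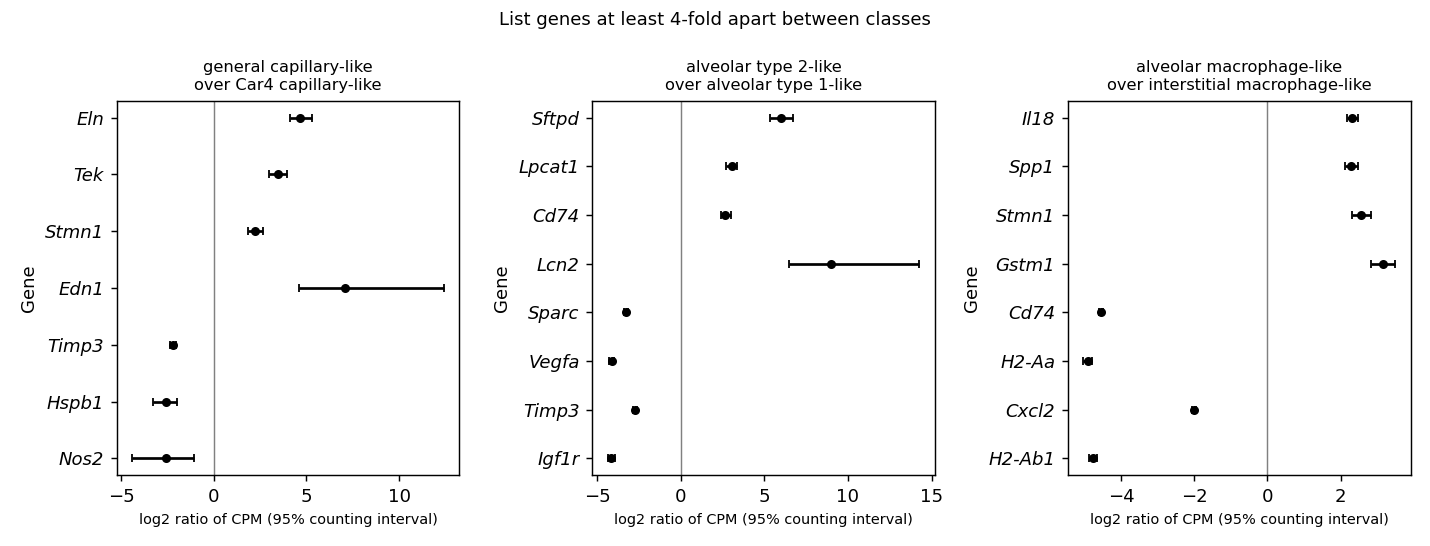
Log2 ratio of CPM between 2 classes (x axis) for the named genes (y axis), with 95% counting intervals as bars and the line of no difference at 0. Points to the right are higher in the class named first in each panel, such as Sftpd at 5.97 in alveolar type 2-like over alveolar type 1-like cells, and points to the left are higher in the class named after it.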

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

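The 5 tests of technical explanations in this part were chosen after the results they bear on had been seen, and no biological explanation was tested, since the cells map to no oxygen group. Across the 8 runs of barcodes, the share of kept cells was looked at for 24 classes and clusters. For 3 of them a single run stood far from the others, measured as its gap to the nearest run over the range of all runs. For independent, normally distributed values chance alone would give about 1.2, or 1 in 20. Shares of cells are skewed and add up to a fixed total within a run, so that rate may not hold here. The 3 were therefore taken as pointers only. B-like cells made up 3.71% of run 7, against 0.861% in the run nearest to it. Natural killer-like cells made up 6.24% of run 3, against 3.56% in the nearest run. That class grew from 332 to 602 cells with 15 neighbours, while T-like cells fell from 670 to 401, and run 3, at 10.6% against 6.70%, then no longer stood apart by the same measure, nor did it with doublets kept (6.09%) or under the stricter cell filter (8.53%). Cluster 27 made up 6.28% of run 6, against 0.0609% in the nearest run.

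Cluster 27 held 106 of its 108 cells in run 6 and joined epithelial genes with the leukocyte gene Ptprc: Rtkn2, an alveolar type 1 gene, was at 341 CPM, or 0.104 times its level in alveolar type 1-like cells (0.0852 to 0.127), the type 2 gene Sftpc was at 6484 CPM, against 1203 CPM in alveolar type 1-like and 122376 CPM in alveolar type 2-like cells, and Ptprc had a UMI in 84.3% of its cells at a median depth of 2222.5 UMIs, against 9.89% of alveolar type 1-like cells at 4968 UMIs. The sum of surfactant transcripts in alveolar type 1-like cells, mostly Sftpc, was 1364 CPM, with 433 CPM without run 4 and 2404 CPM without run 1. Cluster 27 was separate at resolution 2.0 too. With doublets kept, however, 107 of its cells were named alveolar type 1-like. So were 69 of the 71 left by the stricter cell filter, and all 108 with 15 neighbours. The alveolar type 1-like class then held 213, 143 and 211 cells in place of 91. Doublets of an epithelial cell and a macrophage would hold more RNA than the median cell of the run, yet the median UMI count of cluster 27 was 0.519 times that of run 6. Of the list genes that took no part in the clustering, the 9 led by alveolar type 1-like cells were 3.49-fold higher in cluster 27 than in the named immune cells of run 6 (3.04 to 4.003). The 12 led by alveolar type 2-like cells were 6.19-fold higher (5.48 to 6.97). The 8 alveolar type 1 markers other than Rtkn2, which clustering could use, were 14.2-fold higher (12.4 to 16.3) and Rtkn2 99.7-fold (61.9 to 168). Among all genes outside the clustering, those over 10-fold above the immune cells of other runs gave type 1 and type 2 ratios of 3.85 (3.65 to 4.06) and 14.01 (13.4 to 14.7). For those over 100-fold above them, the ratios were 20.5 (18.3 to 22.997) and 24.0 (22.6 to 25.5). Without Sftpc the type 2 ratios were 6.84 (6.31 to 7.41) and 25.3 (21.7 to 29.4), so that gene made up much of the gap at the 10-fold bound. Unequal ratios can thus come from a single gene and from what immune cells express themselves. Free RNA in uneven amounts cannot be told apart from other sources of epithelial RNA. What remains open besides is a difference in how the cells of run 6 were handled, and macrophages that took up epithelial material, which may be a candidate explanation but was not tested, and a cluster found in a single run is not shown to be a cell type.

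Cluster 26, with 478 cells or 4.12% of the kept cells, took the name of no sorted compartment and was led by genes of pluripotent cells: of 9 such genes, picked after the cluster had been seen and none of them in a fixed list, each was at least 178-fold above all other cells, with Dppa5a at 8485 CPM and Pou5f1 at 386 CPM. In the 6 runs whose other cells carried Xist, a Y-linked UMI was found in 42.6% of its cells (36.7 to 48.8; 116 of 272) against 0.160% of the other cells (0.0855 to 0.274), and this argues against the Y-positive cells having come from the same pup as the rest of their run but says nothing of the other cells of the cluster, and 39 of the 272 carried Xist. Y-linked genes, which took no part in the clustering, were at 114 CPM in the cluster and 0.320 CPM in the other cells of these runs, a ratio of 356 (207 to 673), which argues against free RNA spread alike over the droplets as the source of the Y-linked UMIs. Of the cells with at least 10 Dppa5a UMIs, 58.8% held a UMI of the 5 surfactant transcripts, a list that includes the secretory cell marker Scgb1a1. Of lymphocytes at the same mix of runs, the level of free RNA, 35.2% did. With each cell thinned to 2000 UMIs, these shares were 35.9% (30.7 to 41.3, 11 cells left out) and 16.7% (137 left out). Runs 4, 5, 6 and 7 had at least 20 cells on each side. Among them the lymphocyte share was highest in run 6, at 27.3% (17.0 to 39.6), where the thinned share was 70.1% (61.6 to 77.7). It was 12.4% in runs 4, 5 and 7 together (7.91 to 18.1). Singly it was 10.4%, 15.4% and 11.1% there, against 7.95%, 8.88% and 12.9% of lymphocytes. The excess over lymphocytes thus lay mainly in run 6, and its source was not tested. As far as the surfactant UMIs are free RNA, which that excess leaves open, this argues against a library without lung cells as the source of these droplets. With run 8 counted, which had 2 such cells and the highest lymphocyte share, the comparison of runs would have decided nothing. Cells from another animal or a culture could account for the Y-positive cells, a hypothesis without a test of its own.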

How the results depend on the processing

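The alternatives with 15 neighbours, without cluster 26 and without a run of barcodes, and all those on gene folds, ratios, list counts and list sums, were chosen after the data had been seen. A gene fold was followed only where its class kept its name, or its cluster its number, and held at least 20 cells. The genes led by cluster 26 were therefore not followed with doublets kept, under the stricter cell filter or at resolution 2.0. Nor were Saa3 under that filter, lymphatic-like genes with doublets kept and ciliated-like genes without run 3, 4, 6, 7 or 8. In the 734 alternatives that could be followed, all 62 gene folds stayed at a log2 fold of at least 2, the lowest being 2.25. Genes named by fold had been picked at 4-fold or more. Of the 734 values, 151 left the counting interval and 18 moved by over 1 on the log2 scale, by at most 2.15. All 37 ratios between classes kept their direction in 495 alternatives, of which 31 moved by over 1.5 times, and the smallest absolute log2 ratio was 1.53. Of 247 alternatives for the 19 list counts, which here leave cell type markers out, 7 moved by over 1.5 times. The mesenchymal count was 1 with doublets kept and the mitochondrial count was 1 under the stricter cell filter. The metallothionein count was 1 without run 3, 4, 6, 7 or 8, where the ciliated-like class fell under 20 cells and could not lead.

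The shares of cells depended more on the processing, and the causes were not tested except for the denominator, which changes the share by construction, and for the alveolar type 1-like share, which cluster 27 joined in the 3 settings that raised it. As shares of all kept cells, general capillary-like cells made up 2.92%, Car4 capillary-like 1.59%, alveolar type 2-like 6.79%, alveolar type 1-like 0.784%, alveolar macrophage-like 17.9%, nonclassical monocyte-like 14.9%, classical monocyte-like 12.1% and neutrophil-like 5.96%. With doublets kept, epithelial cells made up 9.02% and immune cells 75.0% of all cells, general capillary-like 59.7%, alveolar type 2-like 76.6%, alveolar type 1-like 20%, alveolar macrophage-like 28.99% and nonclassical monocyte-like 18.3% of their compartment. Under the stricter filter, endothelial cells made up 4.89% and immune cells 79.5% of all cells, alveolar type 2-like 75.8%, alveolar type 1-like 19.2%, alveolar macrophage-like 29.97% and neutrophil-like 7.61%. At resolution 2.0 immune cells made up 68.7% and alveolar macrophage-like 26.9%. With 15 neighbours epithelial cells made up 8.78%, alveolar type 2-like 75.9% and alveolar type 1-like 20.7%. Without cluster 26 immune cells made up 73.96%.

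On leaving out each run in turn, endothelial cells ranged from 4.91% to 5.74%, epithelial from 6.84% to 8.37% and immune from 66.4% to 74.4% of kept cells. Within compartments, general capillary-like cells ranged from 51.8% to 57.8%, Car4 capillary-like from 26.1% to 30.5%, alveolar type 2-like from 85.1% to 91.1%, alveolar type 1-like from 6.41%, without run 1, to 12.2%, alveolar macrophage-like from 20.6% to 27.7%, nonclassical monocyte-like from 19.5% to 22.6%, classical monocyte-like from 12.3% to 18.3% and neutrophil-like from 3.78%, without run 1, to 11.7%.

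No paired analysis was possible because the cells map to no library, so the replicate numbers of the labels belong to no column. For the same reason the other planned settings were not run: a different count test, other size factors, no filter on low counts, Xist as a covariate, equal numbers of cells per sample, other list tests and leaving out labelled replicates. Depth limits the ciliated-like class with 21 cells, the lymphatic-like class with 41 and the migratory dendritic-like class with 51, where a gene at 20 CPM rests on few counts.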

Other observations

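The values in this part were looked at after the clusters had been seen, and no test was run on them. Cluster 2 held 540 cells with a median of 10716 UMIs and was set apart by Saa3, Inhba, Gpnmb, Arg1 and Mmp14. Its cells expressed the leukocyte gene Ptprc at 620 CPM and Lyz2 at 8901 CPM. The list genes Fn1, which encodes fibronectin, Il1a, an inflammatory cytokine, and Ctss, a lysosomal protease, were highest in cluster 2, at 2079, 218 and 4370 CPM, which was 4.56-fold, 8.90-fold and 4.25-fold above all other cells and held in 4 of 4 runs for each. These 3 genes were picked after their values had been seen. Cluster 13, with 466 cells, was led by Adamdec1, Dok2, Acp5 and Axl and held Lyz2 at 11869 CPM. Cluster 7, with 254 cells, was led by Arhgap26, Vav3 and Trps1, had the highest level of Ptprc of all classes at 2600 CPM, and held Lyz2 at only 653 CPM.

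Cluster 26 held more than pluripotency genes. The p53 targets Eda2r, Psrc1 and Zmat3 were 61.1-fold, 33.7-fold and 5.97-fold above all other cells there, the fatty acid elongase Elovl6 was 29.7-fold higher, and Mif, a cytokine also counted among HIF targets, was 6.80-fold higher at 1197 CPM, in 4 of 4 runs for each. Of the genes of the sorted compartments, Epcam was at 89.5 CPM (82.0 to 97.4), against 210 CPM in alveolar type 2-like cells, Pecam1 at 108 CPM (99.6 to 117), and Cdh5 at 7.98 CPM (5.86 to 10.6), against 1037 and 1219 CPM in general capillary-like cells, and Ptprc at 22.9 CPM. The names of these genes were likewise picked after their values had been seen.

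Each run of barcodes held some classes at very different shares. Cluster 2 made up 13.8%, 1.07%, 1.51%, 0.792%, 0.807%, 10.95%, 0.766% and 21.0% of the kept cells of runs 1 to 8, so that 3 values lay between 10.95% and 21.0% and the other 5 between 0.766% and 1.51%. Neutrophil-like cells made up 27.1%, 7.47%, 1.61%, 0.609%, 0.161%, 7.70%, 1.32% and 14.7% of runs 1 to 8. Cluster 13 made up 13.3% of run 4 and 9.79% of run 5, against at most 1.21% in the other runs. Interstitial macrophage-like cells made up 7.23%, 0.712%, 5.53%, 2.25%, 2.80%, 14.4%, 1.75% and 2.69% of runs 1 to 8. The runs were not assigned to air or hyperoxia, and these values compare no groups.

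The sex-linked genes separated the runs as well. A UMI of a Y-linked gene was found in 84.4%, 0.355%, 1.10%, 3.37%, 2.65%, 67.7%, 0.328% and 0.299% of the cells of runs 1 to 8, and a UMI of Xist in 0.446%, 83.3%, 82.2%, 66.3%, 78.2%, 0.292%, 77.9% and 70.2%. The sex of the pups is not given in the labels. Outside cluster 26, the share of Y-positive cells in runs 2, 3, 4, 5, 7 and 8 was at most 0.338%. In cluster 26 itself, Y-positive cells numbered 1 of 11 in run 2, 10 of 16 in run 3, 54 of 111 in run 4, 44 of 82 in run 5, 56 of 206 in run 6, 6 of 47 in run 7 and 1 of 5 in run 8, while run 1 held no cell of the cluster.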
